A study of Mus musculus with 2 samples.

How the data were processed

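Poly(A) RNA of dissociated adult mouse testis was measured in 1 WT and 1 Nsun7 knockout library. Per the labels' protocols, testes were minced and digested with enzymes, strained, treated with a lysis buffer and washed, and libraries were made with the DNBelab C series droplet system. The deposited matrices hold whole-number counts per gene and barcode, written by PISA 0.12 per the file headers, and the submitters' processing notes name GRCm38. The aligner, the annotation and any filter on barcodes are not given in the sources used here. The smallest total was 1001 counts per barcode in both matrices. Barcodes are taken as cells, and the counts as UMIs.

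The genotype of each library came from the labels. The 2 matrices listed 29520 and 28743 genes and were joined by symbol, giving 30052 symbols, of which 97.5% are in the GENCODE M21 annotation of GRCm38 that gave coordinates. Barcodes with 200 or more genes and at most 20% mitochondrial counts were kept: 15139 of 16376 in WT and 13869 of 16837 in the knockout library. Doublets were called per library with Scrublet in scanpy 1.11.5 (703 WT and 699 knockout cells, 4.64% and 5.04%) and were kept in the main values. Counts were scaled to 10000 per cell and log transformed, 3000 variable genes per library without Nsun7 were reduced to 40 principal components, and a graph of 20 neighbours was clustered with the Leiden method at resolution 1 (igraph 0.11.9), with no batch correction. This gave 25 clusters. A cluster took the class with the highest mean marker score among classes with at least 3 detected markers. It stayed unnamed where over 50% of its cells were called doublets, where another class had more markers among its 10 leading genes, or where its counts, multiplied by 3, were under the library median with no own marker among those genes. The limit on doublets and the requirement of detected markers were set after the clusters had been seen. The plan fixed beforehand left any cluster with leading genes of 2 classes unnamed. Under the looser rule used here, cluster 13 (the early spermatocyte class) and cluster 19 (the interstitial stroma class) kept their names. The rule on low counts was not in that plan either.

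With 1 library per genotype no test was possible, so counts were summed per library and class and divided by the class total to give CPM, with exact Poisson intervals; fold intervals are exact conditional binomial ones and shares carry exact Clopper-Pearson intervals. Ratios used to rank and count genes add a prior of 5 CPM, and printed folds of named genes do not. Counts of genes at least 2 times apart use genes at a mean of 50 CPM or more and describe these libraries only. Classes with 50 or more cells in each library were compared. The genes named were fixed before the data were examined: Nsun7 and the measured m5C list; in late spermatocytes, round spermatids and elongating spermatids the 10 highest and 10 lowest ratios among genes at 50 CPM with the same sign in every cluster with 100 or more cells in each library, leaving out predicted, mitochondrial and ribosomal protein genes; 3 per side in other classes (3 genes that the rule selects are not reported here); and per list the extreme members and up to 4 of the most abundant. The 20 lists cover RNA m5C writers and readers, 5 parts of the flagellum, the acrosome, chromatin condensation, sperm glycolysis, ion channels, spermatid kinases, meiotic recombination, the piRNA pathway, p53 and apoptosis, immediate early genes, unfolded protein and oxidative stress, steroid synthesis, Sertoli products, mitochondrially encoded genes and ribosomal proteins. List members count from 10 CPM, and list medians were set against 10000 random lists matched in 20 expression bins. Intervals of list medians come from 200 Poisson resamples.

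The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. The counting steps were tested on simulated data with 200 genes changed by known folds. In the simulated late spermatocyte comparison of 3738 genes, 55 of 66 genes changed 3-fold passed the 2-fold rule, 0 of 71 genes changed 1.5-fold and 0 of 3538 unchanged genes did, and the others changed 3-fold lay under the minimum level; intervals covered 95.6% of true ratios. In round spermatids (3808 genes) 60 of 68 and in elongating spermatids (1917 genes) 64 of 71 genes changed 3-fold passed. Intervals covered 95.9% and 93.6% of true ratios in these 2 classes. The simulated counts held Poisson error only, drawn from 1 pooled profile per class, without free RNA, stage mix or differences between animals. The simulation therefore checks the calculation and cannot show how often those sources pass the 2-fold rule.

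Alternatives fixed before the data were examined were a stricter filter (500 genes, 10% mitochondrial counts), no filter (left-out barcodes given the class of their nearest kept neighbours), removal of called doublets, Leiden resolution 2, clustering each library on its own, trimmed mean scaling (30% of ratios and 5% of levels trimmed), equal weight per cell, the same cluster mix in both libraries, minimum levels of 10, 50 and 200 CPM, a prior of 1 CPM and thinning to 500 UMIs. Chosen after seeing the data were counting cluster 6 as round spermatids, cluster 11 as late spermatocytes or round spermatids, barcodes with 5000 or more UMIs, Sertoli-like cluster 12 alone, and subtracting an estimate of free RNA. That estimate multiplies the profile of the whole library by the share at which 4 Leydig genes (Insl3, Cyp17a1, Cyp11a1 and Hsd3b6) appear in the class, 6.97% in WT and 5.38% in knockout elongating spermatids.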

Results

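Single-cell RNA sequencing was carried out on dissociated testes of adult mice, with 1 library from a wild-type (WT) testis and 1 library from an Nsun7 knockout testis. Nsun7 encodes a member of the NOL1/NOP2/SUN family of RNA 5-methylcytosine (m5C) methyltransferase-like proteins, and the series title links it to the assembly of the sperm flagellum. The WT matrix held 16376 barcodes and 220247156 counts, and the knockout matrix held 16837 barcodes and 210531446 counts. After the cell filter, 15139 WT cells with a median of 8723 unique molecular identifiers (UMIs) and 13869 knockout cells with a median of 12020 UMIs remained. With 1 library per genotype, no difference below has a replicate check and none was tested across samples. All intervals are 95% intervals that cover counting error only. Clusters were named from fixed markers, so each class below is to be read as "like" the named type.

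The first comparison asked whether the targeted transcript differed between the libraries. Nsun7 (chromosome 5, 66259897 to 66298026, plus strand, GRCm38, a protein-coding gene) was at 174 CPM (counts per 1000000 counts; interval 172 to 176) in kept WT cells and at 40.9 CPM (40.05 to 41.82) in kept knockout cells, a log2 ratio of -2.09 (-2.12 to -2.05). In WT the transcript was highest in round spermatids at 218 CPM, followed by late spermatocytes at 198 CPM and elongating spermatids at 159 CPM. In the knockout library the same classes were at 41.6, 41.4 and 43.5 CPM, so 4.78-fold, 5.25-fold and 3.64-fold lower in late spermatocytes, round spermatids and elongating spermatids. Spermatogonia were at 34.2 and 11.6 CPM and early spermatocytes at 35.5 and 6.90 CPM. Among somatic classes, macrophages were at 94.4 and 31.8 CPM and Sertoli-like cells at 74.0 and 32.7 CPM. Interstitial stroma was at 68.8 and 16.2 CPM and Leydig-like cells at 26.8 and 4.12 CPM. The WT levels of spermatogonia and early spermatocytes thus lay within the range of these somatic classes. In WT, the 4 Leydig genes stood at 23.1% of their library-wide level in macrophages, 13.5% in stroma and 11.7% in Sertoli-like cells. They stood at 9.89% in early spermatocytes and 8.61% in spermatogonia, and all 5 shares were lower in the knockout library. With Nsun7 at 170 CPM over all WT barcodes, free RNA may be a part of its level in these classes. The labels do not state which part of the gene was deleted, and a 3' tag outside that part would not test the deletion. After thinning every cell to 1000 UMIs, 19.4% of WT and 3.99% of knockout round spermatids held an Nsun7 UMI, against 87.1% and 45.9% before thinning. In Leydig-like cells, a somatic type, the thinned shares were 3.40% in WT (1.77% to 5.86%) and 0.541% in the knockout library (0.066% to 1.94%). Median unthinned depths were 16190 and 13221 UMIs in round spermatids and 9980 and 13742 in Leydig-like cells, in WT and knockout order.

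**Figure D1:**
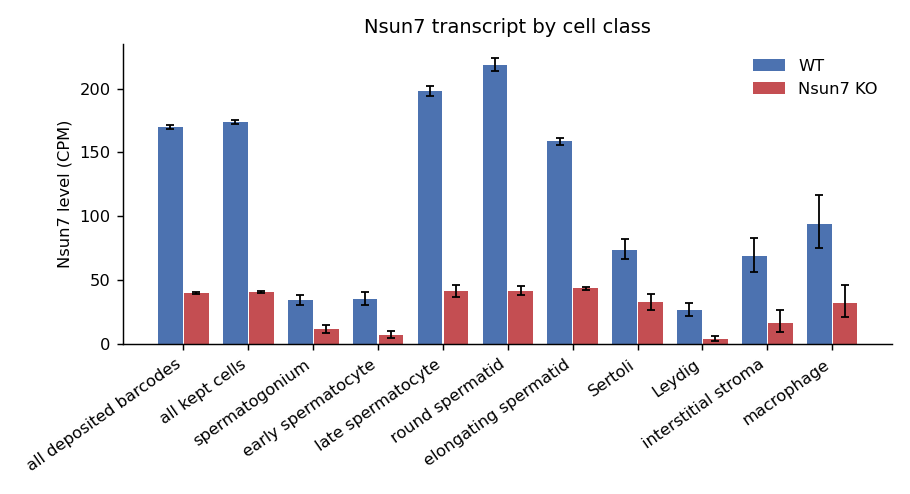
Nsun7 level in CPM (vertical axis) in all barcodes, in all kept cells and in each class, for the WT library (blue) and the knockout library (red). Bars are summed counts over the class total, not corrected for free RNA, and error bars are exact 95% Poisson intervals. The WT bar is the taller in every group, with 218 against 41.6 CPM in round spermatids.

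Other members of the fixed list of RNA m5C writers and readers lay close together in round spermatids. Of 7 measured members there, Nsun7 was the only one 1.5 times or more lower, and none was 1.5 times or more higher. Nsun2, a tRNA and mRNA m5C methyltransferase, was at 134 CPM in WT and 142 CPM in the knockout library, and Nsun4, a mitochondrial rRNA methyltransferase, was at 80.4 and 87.5 CPM. Nsun6 was at 39.9 and 45.4 CPM and Nop2 at 24.1 and 20.5 CPM. Among RNA-binding readers, Ybx1 was at 2775 and 2658 CPM and the germ cell paralogue Ybx2 at 1594 and 1869 CPM. In elongating spermatids Ybx1 was at 762 CPM in WT and 579 CPM in the knockout library, Nsun2 at 23.1 and 17.3 CPM, Nsun4 at 219 and 211 CPM, and Ybx2 at 2084 and 2449 CPM. The list had a median log2 ratio of -0.334 over 5 measured members there, at percentile 0.12 of random lists, and of 0.0 with trimmed mean scaling. The targeted gene Nsun7 is 1 of the 5, so this median and percentile do not describe the other members alone. Of these members, Nsun7 was the only one 1.5 times or more lower. In late spermatocytes Nsun4 was the highest member by ratio, at 15.5 and 26.1 CPM (log2 ratio 0.76, interval 0.52 to 0.99), and Alkbh1 was at 23.7 and 15.6 CPM. Nsun2 (189 and 205 CPM), Ybx1 (3283 and 3033 CPM), Ybx2 (2293 and 2562 CPM) and Nop2 (15.8 and 13.3 CPM) completed that list. Nsun4 was far higher in elongating spermatids, which made up 33.7% of WT and 63.1% of knockout cells. Free RNA may therefore be a part of its ratio in late spermatocytes.

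The composition of the suspensions differed in spermatids, spermatocytes and spermatogonia. Elongating spermatids made up 33.7% (32.98% to 34.49%) of WT cells and 63.1% (62.3% to 63.9%) of knockout cells. Late spermatocytes made up 17.8% (17.2% to 18.4%) and 6.13% (5.74% to 6.54%), and round spermatids 9.54% (9.075% to 10.017%) and 4.33% (4.001% to 4.686%). Spermatogonia were 7.53% and 3.81% of cells and early spermatocytes 7.10% and 3.35%. There were 3.54 elongating spermatids per round spermatid in WT and 14.56 in the knockout library, or 2.30 and 6.63 with unnamed cluster 6, which carries round spermatid genes, counted as round spermatids. There were 0.535 and 0.707 round spermatids per late spermatocyte. Somatic cells together were 11.7% (11.2% to 12.2%) of WT and 9.68% (9.20% to 10.2%) of knockout cells, with endothelial-like cells at 52 and 7 cells. The difference in spermatogonia was 0.499 points in favour of the knockout library when each library was clustered on its own, against -3.72 points in the joint clustering, but that clustering left unnamed a WT cluster of 896 cells with 3 spermatogonium markers among its leading genes. The difference in somatic cells was 6.748 points in favour of the knockout library without the cell filter, against -2.035 points. The barcodes added by that setting took the class of their nearest kept neighbours. Their median mitochondrial share was 39.1% in the knockout library and 29.6% in WT, so their class is uncertain. The labels name a strainer and a lysis step but no sort, so these shares describe the suspensions.

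Within elongating spermatids, 3 of 9 clusters had transition protein 1 (Tnp1) below 10000 CPM with abundant protamine 2 (Prm2), and they held 44.5% (43.1% to 45.8%) of the WT class and 28.6% (27.7% to 29.6%) of the knockout class. Different clusters held the class in the 2 libraries: clusters 0 and 7 were mainly WT (805 and 1448 WT cells against 50 and 77), and clusters 1, 22 and 24 were mainly knockout (1770, 1642 and 1751 knockout cells against 66, 61 and 154). Clusters 2, 3, 4 and 16 held cells of both. A cluster mostly of 1 library may be that library rather than a stage. Unnamed clusters held 12.6% of WT and 9.60% of knockout cells. They were cluster 5, mostly called doublets (1.39% and 2.01%), cluster 6, with low counts and round spermatid genes (5.10% and 5.18%), and cluster 11, between late spermatocytes and round spermatids (6.08% and 2.42%).

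**Figure D2:**
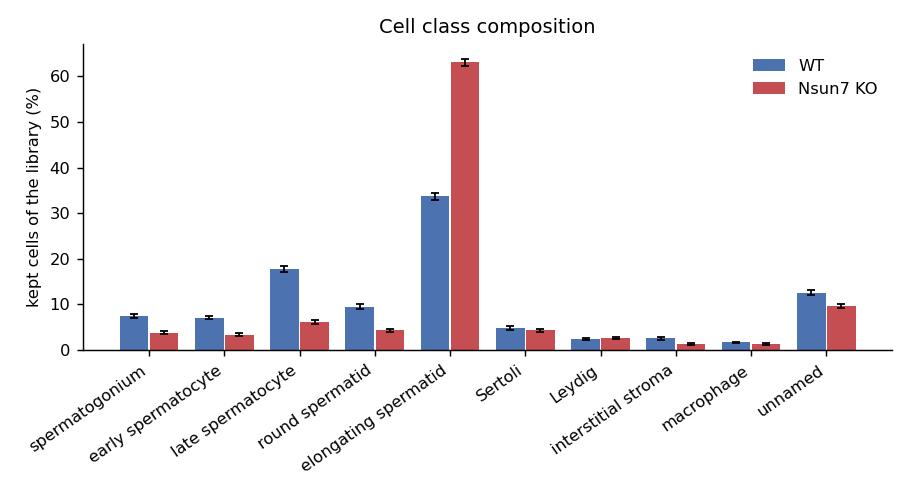
Percent of the kept cells of each library (vertical axis) in each class, for WT (blue) and the knockout library (red), with exact 95% Clopper-Pearson intervals as error bars. Elongating spermatids stand at 33.7% and 63.1%, and late spermatocytes at 17.8% and 6.13%.

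Counts per cell also differed by class. Late spermatocytes had a median of 10144 UMIs in WT and 2797 UMIs in the knockout library. The high-count late spermatocyte clusters 9 and 14 held 64.9% (63.1% to 66.7%) of the WT class and 29.5% (26.5% to 32.7%) of the knockout class, and low-count cluster 17 held the rest. Medians within clusters, in WT and knockout order, were 21275.5 and 12048 UMIs in cluster 9 and 18755 and 11706 in cluster 14. They were 1801.5 and 2000 UMIs in cluster 17, and 12906.5 and 6571 in unnamed cluster 11. Round spermatids had medians of 16190 and 13221 UMIs, elongating spermatids 11690 and 14819, and Leydig-like cells 9980 and 13742. After thinning to 1000 UMIs, the median number of genes per cell was 769 in WT and 758 in knockout late spermatocytes, 804 and 797 in round spermatids, and 513 and 503 in elongating spermatids. Unthinned medians were 3639 and 1626, 4759 and 4190, and 2383 and 2494 genes. All barcodes reached the thinning depth.

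Round spermatid transcriptomes of the 2 libraries were close. Of 3798 genes at a mean of 50 CPM or more, 0 were at least 2 times higher in the knockout library, and 1, Nsun7 itself, was at least 2 times lower. The highest ratios by the fixed rule were those of Spata32 (1.71-fold, interval 1.57 to 1.87), Paqr5 (1.64-fold), the actin bundler Fscn3 (1.49-fold) and protamine 1, Prm1 (1.48-fold, from 3756 to 5575 CPM). Fam71f2 and Car2 (carbonic anhydrase 2) were 1.43-fold higher, Cstl1 1.39-fold, Lelp1 1.38-fold, transition protein 2 (Tnp2) 1.36-fold and Prm2 1.35-fold. Below Nsun7, the lowest ratios were those of calmodulin 2, Calm2 (1.498-fold lower, 1.401 to 1.603), the cohesin subunit Rad21 (1.498-fold), the glucose transporter Slc2a3 (1.46-fold) and the synaptonemal complex protein Sycp3 (1.44-fold). Mrps28 was 1.40-fold lower, Pnmal2 1.35-fold, Snrpf and Diablo 1.33-fold and Hnrnph1 1.31-fold. Only cluster 10 had 100 or more cells in each library in this class. Of the higher genes, Spata32, Cstl1, Lelp1 and Fam71f2 were leading genes of elongating spermatid clusters 22, 1, 16 and 24. Of the lower genes, Slc2a3 and Calm2 were leading genes of late spermatocyte clusters 9 and 14. The 4 Leydig genes stood at 6.49% of their library-wide level in WT round spermatids and 5.32% in knockout ones. Free RNA may therefore be a part of these folds.

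Flagellum genes were measured at nearly the same levels in round spermatids of both libraries. Across 5 flagellum lists together, 168 members were measured, the median log2 ratio was -0.003, at percentile 65.7 of 10000 random lists matched on expression, and 0 members were 1.5 times or more higher or lower. Medians and percentiles here and below describe these 2 libraries. The median was -0.030 for 32 axonemal dynein arm and assembly genes, -0.014 for 37 radial spoke, central pair and nexin link genes, 0.016 for 43 genes of malformed sperm flagella, 0.042 for 34 fibrous sheath and outer dense fibre genes and -0.030 for 47 intraflagellar transport and manchette genes. The sheath anchor Akap4 was at 861 CPM in WT and 889 CPM in the knockout library, Cfap206 at 1313 and 1341, Spata6 at 1017 and 1061, Dnaaf1 at 887 and 844, Meig1 at 5743 and 5623, and Odf2 at 2371 and 2490. The members farthest from 0 were Odf1, an outer dense fibre protein (828 and 1081 CPM, log2 ratio 0.38 with a prior of 5 CPM), and Ift80 (47.6 and 34.1 CPM, -0.43). The dynein arm assembly factor Zmynd10 was at 89.9 and 68.8 CPM.

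The remaining lists in round spermatids had medians between -0.109 and 0.088. Unfolded protein and oxidative stress genes were lowest (20 measured, median -0.109, percentile 0.06), with Pdia3 at 112 and 87.4 CPM and Herpud1 at 60.2 and 74.4 CPM. Chromatin condensation genes had a median of 0.030, with Prm1 highest. The acrosome list was at -0.006 (42 measured), with Spaca1 at 877 and 817 CPM. Sperm glycolysis genes were at -0.011, with Ldhc at 7033 and 6928 CPM, and ion channels and exchangers at -0.038, with Catsperz at 753 and 705 CPM. Spermatid kinases, phosphatases and ubiquitin genes were at 0.043. The piRNA list was at -0.030, and its lowest member Piwil1, the pachytene Piwi protein, was at 19.7 CPM in WT and 9.39 CPM in the knockout library. The synaptonemal complex list was at -0.044, p53 and apoptosis genes at -0.019, immediate early genes at -0.049, steroid synthesis genes at -0.069 and Sertoli products at -0.035. Mitochondrially encoded genes were at 0.053 and ribosomal protein genes at -0.033.

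In elongating spermatids, the lowest ratios of knockout over WT by the fixed rule included those of the histone chaperone gene Nasp and the nucleolar protein gene Lyar. Of 1942 genes at 50 CPM or more, 13 were at least 2 times lower and 0 at least 2 times higher. Lyar was at 165 CPM in WT and 42.1 CPM in the knockout library (3.91-fold lower, 3.79 to 4.03), and Nasp at 110 and 27.5 CPM (4.01-fold). The near-identical tubulin genes Tuba3a and Tuba3b, whose counts may be split between them, were 2.92-fold and 3.14-fold lower. Gkap1 was 2.98-fold lower, Hsp90aa1 2.54-fold, Actg1 2.35-fold and the testis chaperone Clgn 2.32-fold. Leydig-like cells, which are not germ cells, had Lyar at 291 and 71.7 CPM, Nasp at 175 and 48.2 CPM and Tuba3b at 148 and 20.9 CPM, while Actg1 was at 415 and 380 CPM there. The number at least 2 times lower was 4 with the same cluster mix in both libraries, 1 after subtraction of an estimate of free RNA, 6 with trimmed mean scaling, 40 with each library clustered on its own, 103 at a minimum of 10 CPM and 0 at a minimum of 200 CPM. The free RNA predicted from Leydig genes came to 163 of the 165 CPM of Lyar in WT and to 30.9 of the 42.1 CPM in the knockout library, so almost no WT level was left to compare. For Hsp90aa1 it came to 102 of 131 CPM and 21.3 of 51.5 CPM, and the log2 ratio after subtraction was 0.013. The highest ratios were small: Tex50 1.42-fold, Paqr5 1.39-fold, Defb33 1.38-fold, Siah2, an E3 ubiquitin ligase, 1.36-fold and Odf3b 1.34-fold. Hspa1l, Capza3, Tex37, Rffl and Prss58 were each 1.31-fold higher.

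Flagellum lists had medians below 0 in elongating spermatids. The 5 lists together had 113 measured members, a median log2 ratio of -0.164 (percentile 0.0 of random lists, whose median was -0.056), 13 members 1.5 times or more lower and 0 higher. This median was smaller in size with the same cluster mix, after subtraction of free RNA and among members at 50 CPM or more, as given in the part on processing. The same lists together had a median of -0.358 in Leydig-like cells, which build no flagellum, and of -0.381 in early spermatocytes, where 52 of 139 measured members were 1.5 times or more lower. Medians were -0.381 for radial spoke, central pair and nexin link genes (7 of 23 members lower), -0.294 for dynein arm genes (1 of 16), -0.190 for genes of malformed flagella (0 of 29), -0.117 for intraflagellar transport and manchette genes (4 of 33) and -0.067 for fibrous sheath and outer dense fibre genes (2 of 29). Among lower members, Rsph1, singled out after its values were seen, was at 169 and 77.3 CPM, and others had lower levels, with Ccdc39 at 20.6 and 6.99 CPM, Ift43 at 19.5 and 6.42 CPM, Zmynd10 at 26.8 and 10.4 CPM and Tekt4 at 20.2 and 8.53 CPM. Of the abundant members, Akap4 was at 4830 and 4501 CPM, Odf1 at 4829 and 4707, Odf2 at 7677 and 7327, Spata6 at 2523 and 2559, and Hook1 at 1197 and 1205. A trimmed mean scaling between the class sums gave a factor of -0.335 on the log2 scale, and relative to it the median of the 5 lists was 0.170, so the sign of this median depends on the scaling. The median over all genes at 10 CPM or more was -0.071. The factor shifts all genes of the class alike, so the percentile of the lists among random lists does not depend on it. Relative to the factor the medians were 0.041 for dynein arm genes, 0.144 for genes of malformed flagella, 0.217 for intraflagellar transport and 0.268 for fibrous sheath genes, while radial spoke genes stayed below 0 at -0.046.

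Of the other lists in elongating spermatids, Sertoli products had the lowest median, -0.878 over 5 members, with Clu at 69.5 and 33.5 CPM and Cst12 at 48.8 and 23.6 CPM. The piRNA list had a median of -0.549, with Adad1 at 26.9 and 8.47 CPM and Mael at 371 and 300 CPM. Mitochondrially encoded genes were at -0.481, with mt-Co1 at 1740 and 1206 CPM, but at 0.283 with the same cluster mix in both libraries. Unfolded protein and oxidative stress genes were at -0.357 (Hspa5 at 42.8 and 17.1 CPM), p53 and apoptosis genes at -0.408 over 4 members (0.078 for members at 50 CPM or more) and synaptonemal complex genes at -0.207. The acrosome list was at -0.170, with Zpbp2 at 32.6 and 7.80 CPM and Crisp2 at 2754 and 2559 CPM, and glycolysis genes at -0.178, with Slc2a3 at 71.3 and 27.9 CPM. Ion channels were at -0.214, kinases at -0.054, chromatin condensation genes at -0.041, ribosomal proteins at -0.083, immediate early genes at 0.048 and steroid synthesis genes at 0.064. Relative to the trimmed mean factor, the acrosome (0.165), glycolysis (0.157), ion channel (0.121), synaptonemal complex (0.127), chromatin condensation (0.294), kinase (0.281) and ribosomal protein (0.251) medians lay above 0, and the Sertoli product (-0.543), piRNA (-0.214), mitochondrial (-0.146), p53 (-0.073) and unfolded protein (-0.022) medians below 0. Prm1 was at 55706 and 68843 CPM, Tnp2 at 24523 and 30264 CPM, Tnp1 at 48253 and 56102 CPM and Prm2 at 55998 and 51840 CPM.

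**Figure D3:**
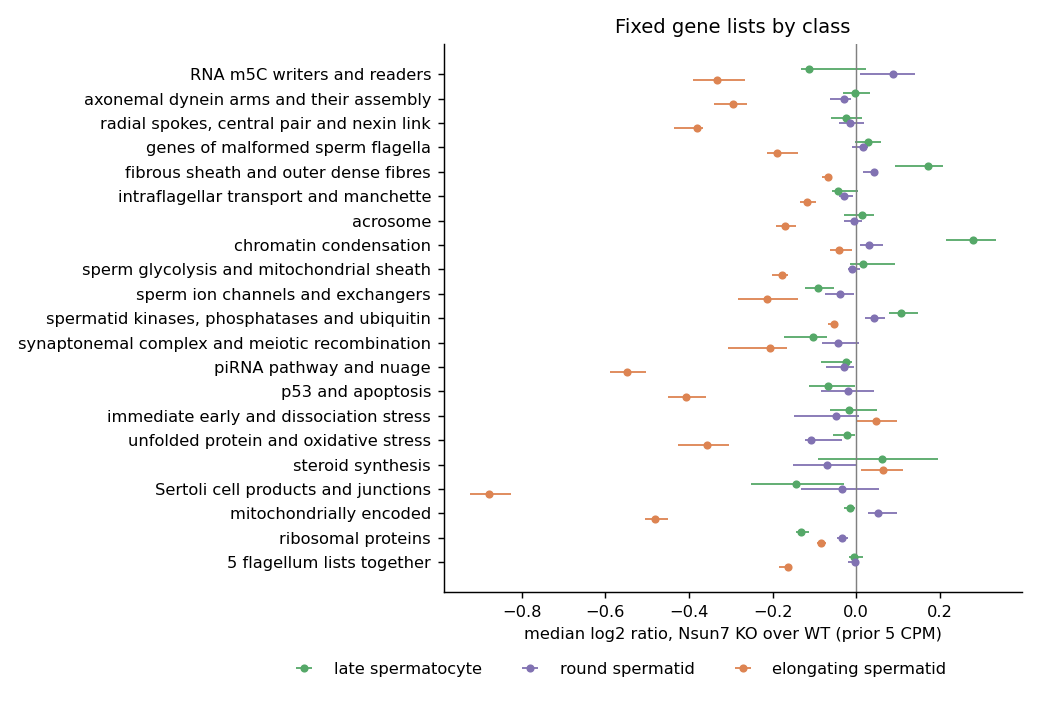
Median log2 ratio of knockout over WT (horizontal axis, prior of 5 CPM) for each fixed gene list and for the 5 flagellum lists together, in late spermatocytes (green), round spermatids (violet) and elongating spermatids (orange). Bars are 95% intervals from resampled counts; medians in round spermatids lie between -0.109 and 0.088, and most of those in elongating spermatids lie below 0 but, relative to a trimmed mean factor of -0.335, mostly above it.

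In late spermatocytes, transcripts of condensing spermatids were higher in the knockout library. Of 3738 genes, 13 were at least 2 times higher, and Nsun7 alone was at least 2 times lower. Prm1 was at 1487 CPM in WT and 3616 CPM in the knockout library (2.43-fold, 2.40 to 2.47), Tnp2 2.16-fold and Tnp1 2.12-fold higher. Hspa1l was 2.19-fold higher, Mex3d 2.13-fold, Actrt2 2.11-fold, Hmgb4 2.10-fold, Gpd2 2.09-fold, the histone variant H2al2a 2.04-fold and Galntl5 2.03-fold. Between Nsun7 and 1.39-fold lay the lower genes: the splicing regulator Tra2a (1.58-fold lower), Tex101 and the heterochromatin protein gene Cbx1 (1.56-fold), Snrpf (1.505-fold), Pnisr (1.48-fold), Hnrnph1 (1.46-fold), Atp5md (1.43-fold) and Glipr1l2 (1.39-fold). The 5 flagellum lists together had a median of -0.004 over 165 members. The chromatin condensation list was at 0.280, fibrous sheath genes at 0.171, synaptonemal complex genes at -0.104 and ribosomal proteins at -0.133. The number of genes at least 2 times higher was 1 among barcodes with 5000 or more UMIs, 1 with the same cluster mix, 1 after subtraction of free RNA, 3 with cluster 11 counted in, 26 without called doublets and 60 with each library clustered on its own. The free RNA predicted from Leydig genes gave a median of 66.5% of the difference over the 13 genes, from 49.1% to 98.7% (Tnp1), with 84.0% for Prm1.

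Secondary comparisons in other classes rested on fewer counts. In spermatogonia 117 of 4127 genes were at least 2 times higher in the knockout library and 6 lower, with Tex37 2.97-fold, Capza3 2.93-fold and Hils1 2.78-fold higher and Rsph1 2.65-fold, Clu 2.53-fold and Cox8c 2.18-fold lower. After subtraction of free RNA the log2 ratios of Rsph1 (0.386) and Cox8c (0.168) lay above 0, and called doublets were 8.86% of WT and 16.1% of knockout cells of this class. In early spermatocytes, with 0 higher and 31 lower of 4498 genes, March11 was 3.70-fold, Pabpc2 3.66-fold and Ldhal6b 3.21-fold lower, and Hist1h2ba 1.75-fold, Plod1 1.65-fold and Klf10 1.60-fold higher. The 4 Leydig genes stood at 9.89% of their library-wide level in WT early spermatocytes and at 5.16% in knockout ones. The 5 flagellum lists had a median of -0.381 there, so free RNA may be a part of the lower values. In macrophages, 29 of 3201 genes were at least 2 times higher and 292 lower. Of germ cell transcripts there, 84 of 149 measured members of the 5 flagellum lists were 1.5 times or more lower (median -0.809), and 4 Leydig genes stood at 23.10% of their library-wide level in WT and 14.99% in the knockout library. The B cell chemokine gene Cxcl13 was at 342 CPM in WT and at 0 counts in the knockout library (at least 78.2-fold lower, the lower limit of the interval), Retnla at 166 CPM and 0 counts (at least 37.7-fold lower), and Cd209f at 167 and 7.07 CPM. Cby3, Ifi47 and Defb36 were 4.05-fold, 3.799-fold and 3.13-fold higher there. Defb36 was a leading gene of elongating spermatid cluster 2 and Sertoli-like cluster 12, so it need not be a macrophage transcript. Cby3 rested on 22 WT and 82 knockout counts and Ifi47 on 20 and 70. Whether these 2 transcripts came from macrophages or from free RNA was not tested. The trimmed mean factor was -0.279 on the log2 scale in macrophages, -0.46 in Sertoli-like cells and -0.181 in spermatogonia, and the folds of these classes are not corrected for it. The class had 251 WT and 188 knockout cells.

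In Leydig-like cells, with 1 higher and 35 lower of 3001 genes, the steroid synthesis list had a median log2 ratio of 0.224 over 19 members (percentile 100 of random lists), with 0 members 1.5 times apart; Star, the cholesterol carrier, was at 2132 and 2699 CPM, Cyp17a1 at 10963 and 12880 CPM and Insl3 at 4101 and 4790 CPM. The lowest member by ratio was Hsd3b1, a core enzyme of steroid synthesis (2601 and 1898 CPM). Etnk2 was 2.03-fold, Klf2 1.80-fold and Alas1, the first enzyme of haem synthesis, 1.65-fold higher, and the germ cell transcripts Tuba3b, Tuba3a and Rsph1 were 7.05-fold, 6.41-fold and 6.40-fold lower. Sertoli-like cells were made up of low-count cluster 12 (632 WT and 583 knockout cells) and cluster 23 (100 and 18 cells), which held 44.0% of the WT and 12.4% of the knockout counts of the class. In both together 340 of 3754 genes were at least 2 times higher and 343 lower. The immediate early genes Egr1 and Jun were 5.95-fold and 4.98-fold lower and the nuclear RNA Malat1 4.38-fold lower. Prm1 there was at 9985 CPM in WT and 31590 CPM in the knockout library, with Defb33 3.86-fold and Tex37 3.63-fold higher, and 22 of 23 Sertoli product genes were 1.5 times or more lower. In cluster 12 alone, chosen after seeing the data, 9 of 21 were, Egr1 was 8.93-fold, Jun 6.57-fold and Malat1 7.73-fold lower, and Prm1 was 2.23-fold, Tex37 2.85-fold and Defb33 2.86-fold higher. Interstitial stroma, with 25 higher and 54 lower of 3625 genes, had Sfrp1 3.76-fold, Cst13 3.35-fold and Dpt 2.68-fold higher, and Tmbim7 3.77-fold, Eid3 3.17-fold and Slc2a3 3.13-fold lower. Cst13 was a leading gene of elongating spermatid cluster 4, and Slc2a3 of late spermatocyte cluster 9. The 4 Leydig genes stood at 13.5% of their library-wide level in WT stroma and 13.2% in knockout stroma, so these 2 transcripts need not be stromal.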

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

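The bounds of the tests in this part were written after the results were seen, except for nucleus-retained RNAs within WT, whose bounds were then also used within the knockout library; of the settings, 5000 or more UMIs and free RNA were chosen after, and no filter, clustering on its own and the same cluster mix before the data were examined. Barcodes over the mitochondrial limit, which the comparisons leave out, made up 17.6% (17.1% to 18.2%) of the knockout library and 7.55% (7.15% to 7.97%) of WT. They drew attention as a signal in unused data above the level of the WT library. Of the left-out barcodes, 2548 of 2968 in the knockout library and 781 of 1237 in WT lay nearest to the low-count Sertoli-like cluster 12.

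The higher share of elongating spermatids and lower share of late spermatocytes in the knockout library may be technical or biological. The difference of 29.4 points in elongating spermatids was 21.2 points with no mitochondrial filter, 32.2 points among barcodes with 5000 or more UMIs and 16.2 points when each library was clustered and named on its own, which left knockout clusters of 775 and 720 cells and a WT cluster of 896 cells unnamed. These values argue against the filter, low-count barcodes or the joint naming as the whole cause. A difference in dissociation or straining, a difference between animals and the genotype stay open, since there is 1 library of each, and the genotype was not tested.

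Late spermatocytes of the knockout library had a median of 2797 UMIs against 10144 in WT. Lower sequencing of the whole library could have given this, but the ratio of medians over the other compared classes had a median of 1.26. Fragments without a nucleus could also hold few counts; within WT, nucleus-retained RNAs in the low-count cluster 17 differed from clusters 9 and 14 by a median log2 ratio of -0.046, percentile 24.5 of random lists. Within the knockout library the same median was -0.093 (percentile 21.6), and both values argue against that source as the whole cause, although these RNAs were lower in the knockout than in the WT class (-0.254) as they were in round spermatids (-0.200). Partial leakage of large cells and a biological loss of intact late spermatocytes were not tested.

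Among the genes past the size limit were 12 genes other than Nsun7 that were at least 2 times lower in knockout elongating spermatids and 13 at least 2 times higher in knockout late spermatocytes. Free RNA from a suspension rich in elongating spermatids may account for much of this: predicted from Leydig genes, it gave 87.1% of the CPM difference (median over 12 genes) in elongating spermatids, but 8.4% of that of Nsun7. In late spermatocytes it gave 66.5% (13 genes), just under the bound of 67% set for the test, so the remainder cannot be assigned. With the same cluster mix in both libraries, the median log2 ratio of the 12 genes went from -1.24 to -0.774, between the bounds set, so a part of the stage mix cannot be told apart from free RNA. An effect of the genotype on these transcripts was not tested.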

How the results depend on the processing

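Counting cluster 6 as round spermatids, cluster 11 as either neighbour, keeping only barcodes with 5000 or more UMIs, Sertoli-like cluster 12 alone and subtracting free RNA were chosen after seeing the data. No paired analysis was possible because there is 1 library per genotype, which also rules out leaving out a replicate and any test. Of 54 recomputed differences in cell shares, 30 stayed within their interval, 21 moved and 3 changed sign. For log2 ratios of single genes these numbers were 940, 378 and 4, and for medians of single lists 577, 247 and 14. Counting cluster 6 or 11 into a class cannot change the shares of the other classes. Part of the 30 shares that stayed was therefore fixed in advance and shows no stability. Except where the construction shows it, the cause was not tested. Depth limits the classes with few cells and genes under 50 CPM.

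With each library clustered on its own, the knockout minus WT share was 0.499 points in spermatogonia (-3.716 in the main values), -1.176 in early spermatocytes (-3.755), -13.423 in late spermatocytes (-11.686), -6.093 in round spermatids (-5.205), 16.239 in elongating spermatids (29.356) and 0.026 in somatic cells (-2.035). There were 60 genes at least 2 times higher in late spermatocytes (13 in the main values) and 40 lower in elongating spermatids (13), and the 5 flagellum lists had medians of 0.021, -0.057 and -0.225 in late spermatocytes, round spermatids and elongating spermatids (-0.004, -0.003 and -0.164). Among barcodes with 5000 or more UMIs the shares in the same order were -2.727, -1.69, -14.504, -7.544, 32.225 and -0.738, and 1 gene was higher in late spermatocytes. The stricter filter gave -2.261 in early spermatocytes, -13.295 in late spermatocytes, -5.999 in round spermatids, 31.125 in elongating spermatids and -2.802 in somatic cells. No filter gave 21.208 in elongating spermatids and 6.748 in somatic cells. Resolution 2 gave -2.96 in early spermatocytes, -14.179 in late spermatocytes and -5.82 in round spermatids, flagellum medians of 0.018 in late spermatocytes and -0.069 in round spermatids, and an m5C list median of -0.008 in round spermatids. With cluster 11 as late spermatocytes their share was -15.348, 3 genes were higher and the flagellum median was 0.034. With it as round spermatids the share was -8.866 and the median -0.038. With cluster 6 as round spermatids the flagellum median was -0.05 and the m5C median -0.01.

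In late spermatocytes 26 genes were higher without called doublets and 30 with equal weight per cell, which also gave 2 lower genes and a flagellum median of 0.023. The same cluster mix gave 1 higher gene there, 4 lower genes in elongating spermatids, flagellum medians of -0.031 in round and -0.092 in elongating spermatids, and 0.283 for mitochondrially encoded genes in elongating spermatids. Subtracting free RNA gave 1 higher gene in late spermatocytes, 1 lower gene in elongating spermatids, flagellum medians of 0.017, 0.009 and -0.074, and ribosomal protein medians of 0.001 in round and 0.025 in elongating spermatids. It turned the log2 ratios of Lyar (1.355, over a WT remainder near 0, so its direction is not to be read) and Hsp90aa1 (0.013) in elongating spermatids and of Rsph1 (0.386) and Cox8c (0.168) in spermatogonia above 0. A minimum of 200 CPM left 3 higher and 0 lower genes in late spermatocytes, 0 lower in round and 0 lower in elongating spermatids, since fewer genes were counted. A minimum of 10 CPM gave 2 lower genes in late spermatocytes and 1 higher and 103 lower in elongating spermatids.

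Trimmed mean scaling gave 6 lower genes in elongating spermatids, and flagellum medians of 0.027, 0.051 and 0.17. It put the medians in elongating spermatids at 0.041 for dynein arm genes, 0.144 for genes of malformed flagella, 0.165 for the acrosome, 0.157 for glycolysis, 0.251 for ribosomal proteins and 0.0 for the m5C list, and ribosomal proteins in round spermatids at 0.021. Lists of genes at 50 CPM or more had medians in elongating spermatids of 0.013 for the acrosome, 0.078 for p53 genes and -0.066 for the flagellum. Nsun7 in all kept cells was at a log2 ratio of -1.911 after thinning to 1000 UMIs (-2.087). Thinning to 500 UMIs gave differences in median genes of -4, -2 and -6 in late spermatocytes, round spermatids and elongating spermatids, against -11, -7 and -10 at 1000.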

Other observations

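The hypothesis on neighbouring genes was written before its result; the list of nucleus-retained RNAs was written, and cluster 12 alone was chosen, after the Sertoli-like values had been seen. RNAs that stay in the nucleus, such as Malat1, Neat1, Pnisr and Luc7l3, had medians below those of random lists in the knockout over WT comparison of the 7 classes examined, by amounts that differed. Over 24 measured RNAs the median log2 ratio was -1.22 in Sertoli-like cells (-0.365 for random lists), where 23 were 1.5 times or more lower, and -1.021 with 22 lower in Sertoli-like cluster 12 alone. It was -0.254 in late spermatocytes (1 of 24 lower by that much) and -0.200 in round spermatids (21 measured, 0 of them 1.5 times apart), both at percentile 0.0 of random lists, and -0.561 over 7 RNAs in elongating spermatids. It was -0.069 in Leydig-like cells (percentile 5.83), -0.116 in early spermatocytes (percentile 0.52, 0 of 25 lower) and -0.228 in spermatogonia, close to the -0.191 of random lists. Macrophages and stroma were not examined.

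Sequence flanking the knockout allele could carry expression differences of its own. In round spermatids, 17 measured genes within 2 Mb of Nsun7 had a median absolute log2 ratio of 0.076, at percentile 41.2 of 7829 windows of as many neighbouring genes, which argues against a regional difference. Ube2k was at 386 CPM in WT and 417 CPM in the knockout library, and Limch1 at 88.4 and 86.0 CPM; both were picked after their values were seen.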
